A study of Micropterus salmoides with 45 samples.

How the data were processed

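The values were taken as deposited: reads per sample scaled to rpm, per the labels, for 266 named miRNAs in 45 libraries, with no raw counts used. Names carry the prefix msa- in the source and are written here without it. Trimming, alignment and the genome build behind the values are not given in the sources used here, so no chromosome positions are printed. The denominator of rpm is not given either: the listed miRNAs of a library sum to between 300084 and 961089 rpm.

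Every library showed a smallest step between its low values, as whole read counts scaled by 1 factor would. From this step the implied depth was 1.01 to 5.57 mega-reads per library, with a median of 2.31. Of the low measured values (12 rpm or less), a median of 98.1% per library (lowest 83.6%) were whole multiples of the step within 0.006 rpm. These depths are inferred from the spacing of values and are not read totals reported by the sequencer.

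In most groups of 3 libraries, 1 value equals the mean of the other 2 (within 0.0101 rpm or 0.1%). Such averaged values carry no information of their own, so they were set to missing, and where all 3 values were identical only 1 was kept. A miRNA at 0 in all 3 libraries of a group was set to missing in that group, since no fold can be computed against it without an arbitrary floor. This left 6920 measured values, and most groups then hold 2 values per miRNA. These steps were decided after the values were seen and before any test between groups was run.

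The miRNAs with a mean of at least 1 rpm over the 45 libraries (228 of 266) were fitted on log2(rpm + 1) with the moderated linear model of limma, with a trend of the variance on abundance, 15 groups and all 45 libraries in 1 fit. The median residual degrees of freedom were 15 and the median residual SD was 0.316 log2. Each comparison was a contrast of group means, and the mean over times was the mean of 5 differences taken within the hour. The change over time was an F-test with 4 numerator degrees of freedom. All tests were two-sided except the F-tests, and p-values were adjusted within each comparison by the Benjamini-Hochberg method. A miRNA is called when its adjusted p is under 0.05. The missing values were handled by a separate fit per miRNA followed by limma's variance moderation, which gave limma's own statistics on complete data.

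The comparisons, the miRNA lists, the rule for naming miRNAs and most alternatives were fixed before the data were examined. The plan assumed counts and named limma on log2(value + 1) for values of any other unit, which is what was run. For the means of severe or moderate hypoxia against control the rule names the 10 largest called rises and 10 largest called falls, and for single times the 5 and 5 whose 3 values do not overlap between groups. Severe against moderate hypoxia has 3 and 3, and the F-tests have the 5 widest ranges. All of these need a mean of at least 10 rpm. The rule adds miR-210, miR-462 and miR-731 everywhere, the 5 most abundant miRNAs, and up to 4 called members of each list by adjusted p.

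The 18 lists group miRNAs by the number in their name. They are hypoxia-associated, liver-enriched, lipid and glucose metabolism, p53 and apoptosis, inflammation, angiogenesis and endothelium, the let-7 family, the miR-17 to miR-92 cluster, the miR-183 cluster, the miR-23, miR-27 and miR-24 clusters, the miR-30 family, and markers of erythrocytes, muscle, neurons, leukocytes, stromal cells, exocrine and endocrine pancreas, and epithelium. Lists overlap, and many members are also expressed in liver. Lists of at least 3 tested members were tested by limma's cameraPR on the moderated statistics (preset correlation 0.01). An estimated correlation and fry beside it used all 3 deposited values.

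Simulated libraries with known answers checked the fit, 20 per setting, with 60 of 228 miRNAs changed in those that held changes (20 at each of 3 fold sizes). With 1 value of 3 replaced at random and a spread of 0.3 log2, 4.58% of unchanged miRNAs had an unadjusted p under 0.05 at 12 h, against 25.0% when all 3 values were counted. There 16.5% of 1.5-fold, 59.0% of 2-fold and 99.8% of 4-fold changes were called. When the replaced value was instead the one farthest from the other 2, at a spread of 0.6 log2, the share of unchanged miRNAs was 39.4%, with a mean of 64.6 false calls at 12 h and 69.2 for the mean over times. Standard errors had to be widened 2.39 times to bring that share back to 5%. Further runs with no changed miRNAs, each rule at both spreads, gave 4.06% and 4.61% at 0.3 and 0.6 log2 for random and 42.95% and 40.3% for farthest replacement at 12 h. The depositor's replacement rule is not given in the sources used here, so p-values may be too small, and counts with widened standard errors are printed beside the others.

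Rescaled values divide each library by its listed total, or by the median of its ratios to the mean library, and rescaling without further words means the listed total. Analyses ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.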

Results

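Small RNA was sequenced from the liver of largemouth bass kept at normal oxygen, moderate hypoxia or severe hypoxia. Dissolved oxygen was 7.0 mg/L in the control group, 3.0 mg/L in moderate hypoxia and 1.2 mg/L in severe hypoxia. Livers were sampled at 0, 4, 8, 12 and 24 h, where 0 h follows the lowering of oxygen with nitrogen over up to 2 h. Each of the 15 groups of oxygen level and time has 3 libraries, 45 in all. Each oxygen level had 3 tanks in all, and the labels do not link libraries to tanks or fish. The p-values measure only the spread between libraries, and tank cannot be parted from oxygen. A group with 1 measured value takes its spread from the other groups. Values are in rpm for 139 miRNAs named as the 5p arm and 127 named as the 3p arm of their precursor. Means are over the measured values of a group with their SD and n. For a mean over times, the SD and n = 5 refer to group means.

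The most abundant miRNA was miR-26a-5p, with a mean of 82806 rpm and 13.3% of the listed total (8.86% to 19.7% between libraries). It was followed by miR-192-5p, a miRNA abundant in liver and gut, with 65142 rpm and 10.1% (0.599% to 18.2%). Next came miR-181a-5p with 59849 rpm, let-7a-5p with 36901 rpm and miR-22a-3p with 33556 rpm. These 5 together held 44.2% of the listed total (34.4% to 52.8%). The inferred depth was 1.01 to 5.57 mega-reads per library.

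Of 3607 sets of 3 values above 0, 1 value was the mean of the other 2 in 3089 (85.6%), and all 3 were identical in 406 (11.3%). Only 112 sets (3.10%) were of neither kind. Most groups therefore rest on 2 measured values per miRNA. A further 383 sets were listed at 0 in all 3 libraries, and 68 miRNAs were at 0 throughout at least 1 group. Some of these were abundant elsewhere: let-7b-5p was listed at 1338 rpm in moderate hypoxia at 4 h and at 0 in the other 14 groups, and miR-221-3p was at 0 only in moderate hypoxia at 24 h, against 1518 to 3898 rpm in the other groups.

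The summed rpm of the listed miRNAs differed between groups. Sums hold averaged values, so SDs are not of 3 independent libraries. In the control group it was 630942 ± 17864 at 0 h, 795919 ± 46026 at 8 h and 333215 ± 30245 at 24 h (SD, n = 3). Moderate hypoxia gave 474405 ± 43303 at 4 h, 441080 ± 34307 at 8 h and 942465 ± 16810 at 12 h. Severe hypoxia gave 566928 ± 27942 at 0 h, 784474 ± 23945 at 4 h and 533368 ± 8089 at 24 h. Since the denominator of rpm is not given, miRNA counts are given as deposited and after rescaling to the listed total, with the median log2 difference of all tested miRNAs.

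**Figure D1:**
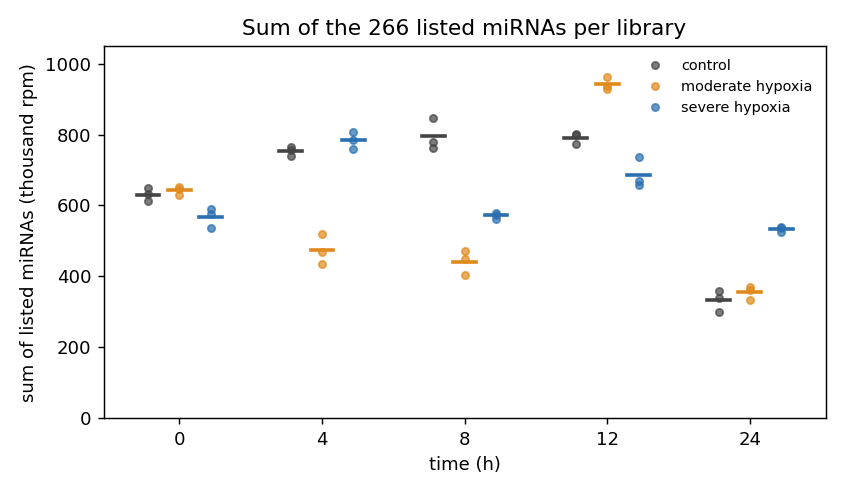
Sum of the listed miRNAs in each library (rpm) by hour and oxygen level, with bars at the group means. The control group at 24 h (333215 rpm) and moderate hypoxia at 12 h (942465 rpm) are the lowest and highest group means.

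The miR-126 pair, miRNAs of endothelial cells, was near 0 in some groups and far higher in all others. miR-126b-3p had a mean of 12.3 rpm in the control group at 4 h, 65.3 rpm at 12 h and 6.38 rpm at 24 h, and 13.0 rpm in moderate hypoxia at 8 h, against at least 4400 rpm in the other 11 groups. miR-126a-3p stood at 18.9 rpm in severe hypoxia at 8 h and 11.9 rpm in moderate hypoxia at 24 h, against at least 3580 rpm elsewhere. In severe hypoxia at 24 h miR-126b-3p had 1 value in all 3 libraries, 7863 rpm, which is also the value of severe library 1 at 4 h. The 5p arms of the same precursors did not follow: relative to the listed total, their median in the groups with a low 3p arm was 0.761 (miR-126a-5p) and 0.789 (miR-126b-5p) of that in the other groups. Both 5p arms were within 5% of each other in 3 of these 6 groups, where their reads may be shared.

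**Figure D2:**
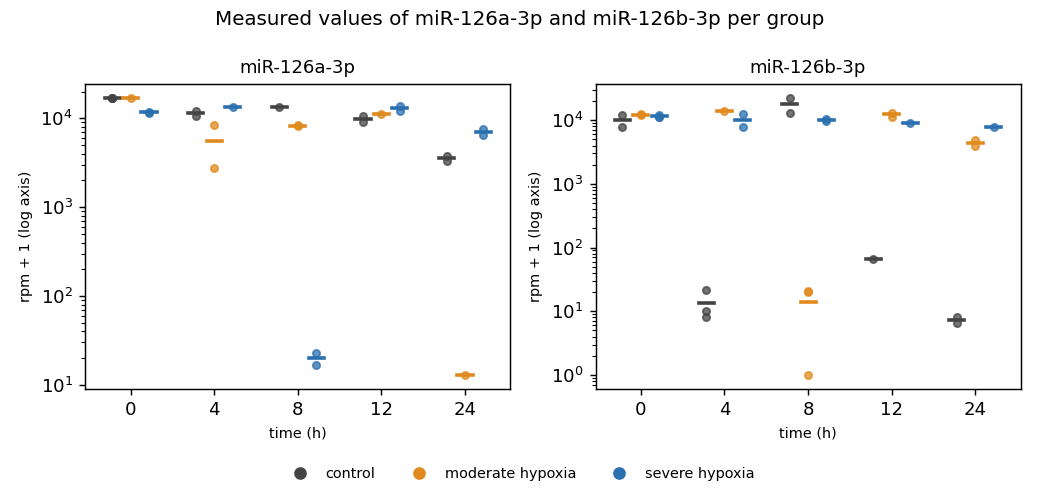
miR-126a-3p and miR-126b-3p in each measured value (rpm + 1, log axis) by hour and oxygen level. Values of miR-126b-3p lie under 100 rpm in 3 control groups and 1 group of moderate hypoxia, and of miR-126a-3p in 1 group of each hypoxia level.

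The control group gives the background of time, fasting and handling at normal oxygen. Within it, miR-181a-3p fell from 1064 rpm at 0 h to 28.9 rpm at 24 h (range 5.16 log2, adjusted p = 9.38e-07). Also called were miR-92b-5p (477 rpm at 8 h, 48.5 at 24 h; adjusted p = 3.18e-06), miR-100-5p (29530 rpm at 4 h, 3018 at 24 h; adjusted p = 1.81e-07) and miR-190a-3p (26.3 rpm at 4 h, 1.91 at 24 h; adjusted p = 2.11e-08). miR-126b-3p had the widest range (11.2 log2, adjusted p = 2.29e-09) through its 3 control groups near 0. The hypoxia-associated miR-210-3p (339 rpm at 4 h, 94.2 at 24 h; adjusted p = 0.000723), miR-210-5p (215.7 and 52.8 rpm; adjusted p = 0.000147) and miR-462-5p (8439 rpm at 8 h, 1607 at 24 h; adjusted p = 4.73e-05) changed over time in control fish too, with adjusted p = 0.0205, 0.0310 and 0.0262 after rescaling to the listed total, which itself was lowest at 24 h. In total 163 miRNAs (78.4% of those tested) changed over time, 121 after rescaling to the listed total, 119 with median-of-ratios scaling and 15 with widened standard errors.

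Severe hypoxia was compared with control as a mean over the 5 times, to find average differences. miR-155-5p, a miRNA of activated immune cells, was higher at 5 of 5 times, at 14.8 ± 6.86 rpm against 5.99 ± 1.58 (log2 1.10, SE 0.20, adjusted p = 0.000303). miR-122-3p, minor arm of the main hepatocyte precursor, stood at 221.4 ± 217.1 rpm against 98.3 ± 38.3 (log2 0.91, SE 0.12, adjusted p = 1.87e-05), higher at 4 of 5 times and most at 12 h. The 5p arm (library mean 8794 rpm) was not called. miR-2188-3p fell to 55.0 ± 60.9 rpm from 96.8 ± 52.4 (log2 -1.08, SE 0.14, adjusted p = 1.28e-05) and was lower at 4 of 5 times. miR-210-3p and miR-210-5p, induced by hypoxia-inducible factor in many vertebrates, were higher on average (log2 0.48 and 0.50, SE 0.15 and 0.16, adjusted p = 0.0240 for both), but at only 3 and 2 of the 5 times, and miR-210-5p was not called without 24 h (log2 0.30, adjusted p = 0.199). miR-462-5p, of a precursor cluster that responds to low oxygen in fish, had 3692 ± 1302 rpm against 4710 ± 2619 (log2 -0.23, adjusted p = 0.294). miR-731-5p was at 0 in 10 of the 15 groups and could not be compared. Leaving out 1 library ended these calls for miR-210-3p (6, adjusted p up to 0.0594) and miR-210-5p (6, up to 0.0636), the first number counting such libraries. Without 12 h miR-122-3p moved to log2 0.54 (adjusted p = 0.0121) and the calls of miR-210-3p (0.11, adjusted p = 0.707) and miR-210-5p (0.04, adjusted p = 0.916) ended, and without 4 h that of miR-210-3p (0.41, adjusted p = 0.0811). miR-2188-3p was at -0.71 without 8 h and -1.68 without 0 h, miR-210-3p at 0.79 without 8 h and miR-210-5p at 0.82 without 0 h.

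Other rises were miR-27c-5p (log2 0.86, 5 of 5 times), miR-126b-5p (0.82), let-7a-3p (0.66), miR-141-3p (0.57, 5 of 5 times), miR-107b-3p (0.54) and miR-30b-5p (0.51; 0.27 and adjusted p = 0.257 without 24 h). Further falls were miR-9-5p (log2 -0.98), miR-30a-3p (-0.82), miR-144-5p (-0.69), miR-19a-3p (-0.57), let-7f-3p (-0.55), miR-456-3p (-0.53), miR-301c-3p (-0.51) and miR-19b-3p (-0.50). The miR-126 pair gave a mean of log2 5.26 for miR-126b-3p and -1.67 for miR-126a-3p, set by the groups near 0. In all, 53 miRNAs (26.4% of those tested) were called, 23 higher and 30 lower, and the same 53 were called in the same direction after rescaling to the listed total (59 called). Scaling by the median of ratios gave 59, 29 higher and 30 lower. Widened standard errors left 3 called, among them miR-19d-5p (log2 -1.57, lower at 5 of 5 times). When the spread between times served as the error, limma called 0 miRNAs, with 10 at an unadjusted p under 0.05 and a smallest adjusted p of 0.171 for miR-155-5p. Single libraries also ended the calls of miR-141-3p (6, adjusted p up to 0.0659), miR-30b-5p (2, up to 0.0519) and miR-107b-3p (1, up to 0.0623), with the number of such libraries first. Without 12 h 25 miRNAs were called, against 65, 55, 51 and 62 without 24, 8, 4 and 0 h. The calls that ended without 12 h include miR-126b-5p (log2 0.53), miR-141-3p (0.29), miR-30b-5p (0.26), miR-9-5p (-0.50), miR-144-5p (-0.62), miR-19a-3p (-0.24), let-7f-3p (-0.11) and miR-456-3p (-0.11). Also ended were miR-144-5p (-0.19) and miR-126a-3p (0.26) without 8 h, and miR-107b-3p without 4 h (0.34) or 0 h (0.41). Still called but moved were miR-107b-3p without 12 h (0.85), miR-144-5p without 0 h (-1.21) and let-7f-3p without 24 h (-0.84).

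**Figure D3:**
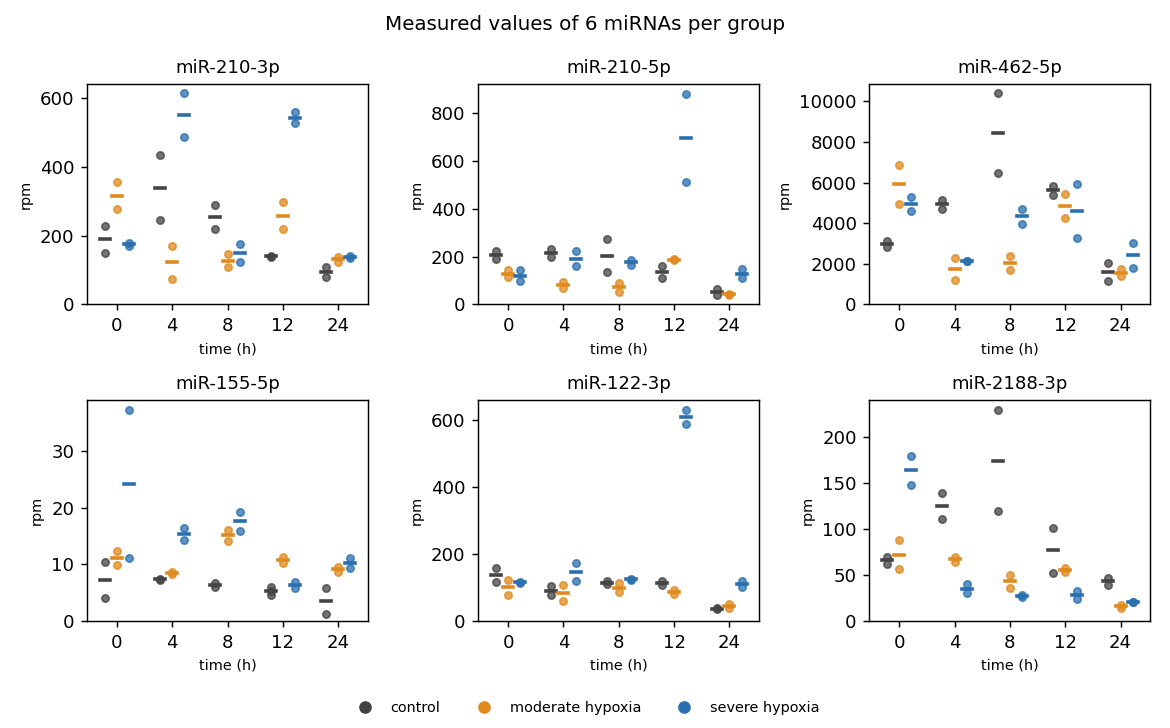
Measured values (points) and group means (lines) of miR-210-3p, miR-210-5p, miR-462-5p, miR-155-5p, miR-122-3p and miR-2188-3p in rpm by hour and oxygen level. At 12 h, severe hypoxia reaches 694 rpm for miR-210-5p and 609 rpm for miR-122-3p, against 136 and 113 rpm in control.

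By 12 h of severe hypoxia, miR-122-3p had risen to 609 ± 28.9 rpm from 113 ± 7.94 in control (n = 2 each; log2 2.42, SE 0.28, adjusted p = 2.43e-06). miR-210-5p rose to 694 ± 262 rpm from 136 ± 35.2 (log2 2.32, SE 0.35, adjusted p = 6.01e-05) and miR-210-3p to 543 ± 20.99 from 140 ± 1.99 (log2 1.94, SE 0.34, adjusted p = 0.000238). let-7e-5p fell to 9690 ± 2222 rpm from 41080 ± 477 (log2 -2.10, SE 0.24, adjusted p = 2.43e-06). Also lower were miR-9-5p (log2 -2.89), let-7f-3p (-2.33), miR-456-3p (-2.21) and miR-10a-5p (-2.02), and miR-126b-5p was higher (1.97) as was miR-126b-3p (7.09, against a control group at 65.3 rpm), both with 1 measured value in each group, so that their spread comes from other groups. Of the let-7 family, 8 of 17 tested members were lower and 1 higher (9 adjusted over the list alone), and of the neuron markers 4 of 7 were lower (4 adjusted over the list alone). In all 69 miRNAs (32.4% of those tested) were called, 21 higher and 48 lower (median log2 -0.23), and 70 after rescaling, 28 higher and 42 lower (median -0.05). With median-of-ratios scaling 67 were called, 33 higher and 34 lower (median 0.02), so the excess of lower calls depends on scaling. With widened standard errors 0 were called, with 81 at an unadjusted p under 0.05 in limma before widening. A single library ended the call of miR-10a-5p (control 1 or severe 1, 2: adjusted p = 0.0583 to 0.125).

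At 0 h, when severe hypoxia had just been reached, miR-460-5p stood at 275 ± 51.6 rpm against 86.4 ± 51.4 in control (n = 2 each; log2 1.79, SE 0.42, adjusted p = 0.0139). miR-460-3p rose with it (371 against 142.4 rpm, log2 1.48), as did the erythrocyte marker miR-144-3p (3543 against 1102 rpm, log2 1.68) and miR-155-5p (24.2 against 7.31 rpm, log2 1.49). miR-137-3p was at 30.9 against 3.39 rpm with 1 measured value each (log2 2.86). The pancreas markers miR-216a-5p (3.45 against 16.1 rpm, log2 -2.08) and miR-216b-5p (49.98 against 180.7 rpm, log2 -1.85) fell, making 2 of 6 tested pancreas markers lower (3 adjusted over the list alone). Leukocyte markers moved too, with miR-155-5p, miR-142a-3p (log2 0.71) and miR-142b-3p (0.71) higher of 6 tested (3 adjusted over the list alone), 3 also after rescaling. The last 2 have nearly identical values in all libraries and count as 1 measurement. miR-135c-5p (-1.26) and miR-27a-3p (-0.74) were lower as well, the latter not called after rescaling (adjusted p = 0.0548). In total 17 miRNAs (7.80% of those tested) were called, 12 higher and 5 lower (median log2 0.02), and 23 after rescaling, 19 higher and 4 lower (median 0.18), or 18 with median-of-ratios scaling, 13 higher and 5 lower. Without control library 3 the count was 9, without severe library 1 it was 8 and without severe library 2 it was 10. With widened standard errors 0 were called, with 47 at an unadjusted p under 0.05 in limma before widening. Without 1 library a call was lost or moved by over 1.5 times for miR-460-5p (control 3 or severe 1, log2 1.15 without control 3, adjusted p = 0.0971 to 0.162), miR-144-3p (control 2, 3 or severe 1, 2: adjusted p = 0.0727 to 0.0949) and miR-155-5p (control 1, 3 or severe 1, 2, 3, log2 0.91 and 0.67 and 2.31 without control 1 and severe 1 and severe 3, adjusted p = 0.00640 to 0.466). The same held for miR-460-3p (control 3 or severe 1, log2 0.90 without control 3, adjusted p = 0.0862 to 0.162), miR-216a-5p (control 1 or severe 3, log2 -1.36 without severe 3, adjusted p = 0.0589 to 0.108) and miR-27a-3p (control 1 or severe 1, 3: 0.0928 to 0.203).

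At 4 h of severe hypoxia, miR-107b-3p rose to 110 ± 12.4 rpm from 42.5 ± 3.39 (n = 2 each; log2 1.35, SE 0.38, adjusted p = 0.0395), and miR-737-5p to 234 from 89.5 rpm (log2 1.36). miR-216a-5p (log2 1.63) and miR-27c-5p (1.52) were also higher. miR-462-5p fell to 2154 ± 5.42 rpm from 4925 ± 290 (log2 -1.19, SE 0.35, adjusted p = 0.0405). The leukocyte marker miR-150-5p fell to 5.27 from 137.3 rpm (log2 -4.46), while miR-2188-3p (-1.80), miR-7a-5p (-1.40) and miR-365-3p (-1.18) were lower too. miR-126b-3p was higher by log2 9.66 against a control group at 12.3 rpm. Called were 14 miRNAs (6.34% of those tested), 6 higher and 8 lower, 15 after rescaling, 6 higher and 9 lower, and 13 with median-of-ratios scaling, 6 higher and 7 lower. The count was 8 without control library 1, 7 without control library 3, 8 without severe library 1 and 5 without severe library 2, and 1 with widened standard errors. Calls lost without 1 library were those of miR-216a-5p (control 1, 2 or severe 1, 2: adjusted p = 0.0766 to 0.230), miR-27c-5p (control 2 or severe 2: 0.0710 to 0.118) and miR-737-5p (control 2, 3 or severe 2: 0.0713 to 0.158). The same held for miR-107b-3p (control 1, 2, 3 or severe 1, 2, 3: 0.0540 to 0.191), miR-150-5p (control 3: 0.0528) and miR-7a-5p (control 1, 3 or severe 1, 2, 3: 0.0570 to 0.302). It held too for miR-462-5p (control 1, 2, 3 or severe 1, 2, 3: 0.0577 to 0.168) and miR-365-3p (control 1 or severe 1, 2: 0.0570 to 0.0855).

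Severe hypoxia at 8 h raised miR-10a-5p to 2705 ± 360 rpm from 191 ± 6.40 (n = 2 each; log2 3.81, SE 0.67, adjusted p = 0.000215). miR-182-5p rose to 461.5 ± 40.2 from 48.2 ± 0.410 rpm (log2 3.23, SE 0.30, adjusted p = 9.03e-08), and both tested members of the miR-183 cluster were higher (2 adjusted over the list alone). miR-7a-5p (log2 3.85), miR-222a-3p (1.58) and miR-155-5p (1.34) rose. The erythrocyte markers fell, miR-144-3p to 216.3 from 2584 rpm (log2 -3.53) and miR-144-5p to 277 from 1890 rpm (log2 -2.70), so that 2 of 2 were lower (2 adjusted over the list alone). Both are arms of 1 precursor and not independent markers. miR-2188-3p (-2.57) and miR-204-5p (-2.35) fell with them, and miR-126a-3p was lower (-9.41, 1 measured control value) through its group at 18.9 rpm. In all 51 miRNAs (23.6% of those tested) were called, 12 higher and 39 lower (median log2 -0.28), and 32 after rescaling to the listed total, 17 higher and 15 lower (median 0.12), 33 with median-of-ratios scaling, 13 higher and 20 lower, and 3 with widened standard errors. Leaving out 1 library ended the calls of miR-222a-3p (control 2, log2 1.03, adjusted p = 0.0576) and miR-155-5p (control 1, 2 or severe 1, 2: adjusted p = 0.0774 to 0.147).

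After 24 h of severe hypoxia, miR-222a-3p, a miRNA that acts in endothelium, stood at 4475 ± 1352 rpm against 740 ± 316 (n = 2 each; log2 2.63, SE 0.34, adjusted p = 1.07e-05). miR-460-3p (616 against 140.8 rpm, log2 2.13), miR-365-3p (1.73) and miR-217-5p (1.75) were higher, the last not after rescaling (adjusted p = 0.118). miR-210-5p had 128.2 against 52.8 rpm (log2 1.29, adjusted p = 0.00791; 0.60 and 0.179 after rescaling). miR-10a-5p (log2 -2.12), miR-9-5p (-2.12), miR-7a-5p (-1.68) and miR-2188-3p (-1.02) fell, and 4 of 7 neuron markers were lower (5 adjusted over the list alone). miR-126b-3p differed by log2 10.07 from a control group at 6.38 rpm, on 1 severe value that is also listed at 4 h. The direction of the whole set turned with scaling: 72 miRNAs (33.8% of those tested) were called, 59 higher and 13 lower (median log2 0.45), against 59 after rescaling, 13 higher and 46 lower (median -0.19), and 55 with median-of-ratios scaling, 20 higher and 35 lower. Of the 72, 26 were called the same way after rescaling and 5 changed sign. Without control library 2 the count was 47, and with widened standard errors it was 0, with 99 at an unadjusted p under 0.05 in limma before widening. Single libraries ended or moved by over 1.5 times the calls of miR-217-5p (control 3 or severe 2: adjusted p = 0.0670 to 0.0858), miR-10a-5p (control 2 or severe 1, 2, log2 -3.54 and -0.70 without severe 1 and severe 2, adjusted p = 0.000693 to 0.40) and miR-9-5p (control 1, log2 -1.37, adjusted p = 0.0526). The same held for miR-7a-5p (control 3 or severe 1, log2 -1.08 without control 3, adjusted p = 0.0508 to 0.0568), miR-2188-3p (control 1 or severe 1, 2: 0.0658 to 0.0827) and miR-210-5p (control 2 or severe 3: 0.0623 to 0.107).

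Moderate hypoxia was compared with control in the same ways, which shows what a milder loss of oxygen goes with. As a mean over the times, miR-155-5p was again higher at 5 of 5 times, at 10.95 ± 2.58 rpm against 5.99 ± 1.58 (log2 0.85, SE 0.20, adjusted p = 0.00265). miR-222a-3p rose to 4201 ± 2616 from 2753 ± 1418 rpm (log2 0.66, SE 0.15, adjusted p = 0.00254). miR-30a-3p fell to 60.4 ± 32.9 from 124.9 ± 64.2 rpm at 5 of 5 times (log2 -1.06, SE 0.15, adjusted p = 2.68e-05) and miR-181a-3p to 78.5 ± 48.4 from 456 ± 527 rpm (log2 -1.61, SE 0.28, adjusted p = 0.000327). miR-210-5p was lower (102 against 163 rpm, log2 -0.67, SE 0.16, adjusted p = 0.00317), miR-210-3p stood at 191 against 203.6 rpm (log2 -0.09, adjusted p = 0.701), and miR-462-5p was lower only as deposited (log2 -0.57, adjusted p = 0.00943; 0.113 after rescaling). The calls of miR-210-5p and miR-462-5p ended without 8 h (log2 -0.47 and -0.20) or 4 h (-0.48 and -0.32), and that of miR-222a-3p without 0 h (0.37). miR-181a-3p (-1.04) and miR-462-5p (-0.95) moved without 0 h.

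The epithelial miR-205-5p (log2 0.79), the muscle miRNA miR-133a-3p (0.46) and miR-27b-3p (0.23) were also higher, none of them called when 24 h was left out (adjusted p = 0.192, 0.136 and 0.976), where miR-27b-3p turned to -0.0049. Lower were miR-2188-3p (log2 -0.90), miR-144-5p (-0.87), miR-204-5p (-0.74) and miR-99-5p (-0.72), and, only as deposited, miR-2188-5p (-0.77), miR-192-5p (-0.76) and miR-9-5p (-0.72; -0.44 and adjusted p = 0.172 without 24 h). The miR-126 pair, near 0 in the groups named above, gave 3.21 for miR-126b-3p and -1.97 for miR-126a-3p (-0.44 and adjusted p = 0.113 without 24 h). Most of the count depends on scaling: 74 miRNAs (37.6% of those tested) were called, 12 higher and 62 lower (median log2 -0.17), against 33 after rescaling to the listed total, 19 higher and 14 lower (median 0.04), with 26 called the same way in both, and 49 with median-of-ratios scaling, 16 higher and 33 lower. Widened standard errors left 1 called. With the spread between times as the error limma called 0 miRNAs, with 10 at an unadjusted p under 0.05 and a smallest adjusted p of 0.675, for miR-155-5p. Single libraries ended the calls of miR-133a-3p (12, adjusted p up to 0.105), miR-27b-3p (15, up to 0.126) and miR-192-5p (5, up to 0.0733), with the number of such libraries first. Without 24, 12, 8, 4 and 0 h the count was 54, 77, 42, 47 and 86. Ended without 8 h were the calls of miR-205-5p (log2 0.63), miR-144-5p (-0.58), miR-204-5p (-0.33), miR-2188-5p (-0.49) and miR-192-5p (-0.72; -0.30 without 4 h). Without 12 h those of miR-133a-3p (0.16) and miR-27b-3p (0.20; 0.38 and called without 8 h) ended, and miR-126b-3p lay between 1.48 without 4 h and 6.81 without 8 h.

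At 0 h of moderate hypoxia, miR-222a-3p stood at 8324 ± 1561 rpm against 2362 ± 601 (n = 2 each; log2 1.83, SE 0.34, adjusted p = 0.00187). miR-21-3p (116 against 40.3 rpm, log2 1.58), miR-141-3p (1.37) and miR-24-3p (1.20) rose, and miR-137-3p was at 86.5 against 3.39 rpm with 1 measured value each (log2 4.32). miR-181a-3p fell to 69.9 ± 7.44 from 1064 ± 15.6 rpm (log2 -3.91, SE 0.63, adjusted p = 0.00111), and miR-135c-5p was lower (-0.80). Higher were 6 of 17 tested inflammation members (1 lower), 3 of 6 leukocyte markers and 4 of 10 epithelium markers. Adjusted over the list alone 8, 4 and 4 were called, and after rescaling 5, 3 and 4 were higher. miR-142a-3p and miR-142b-3p count as 1 measurement. Called were 37 miRNAs (17.1% of those tested), 33 higher and 4 lower (median log2 0.31), and 42 after rescaling, 35 higher and 7 lower (median 0.28). Median-of-ratios scaling gave 25, 8 higher and 17 lower, so these list rises cannot all hold there. The count was 21 without control library 3, 21 without moderate library 1, 13 without moderate library 2 and 0 with widened standard errors (82 at an unadjusted p under 0.05 in limma before widening). Leaving out a library ended the calls of miR-21-3p (control 3 or moderate 1, 2: adjusted p = 0.0626 to 0.174), miR-141-3p (control 3 or moderate 1, 2: 0.0837 to 0.169) and miR-135c-5p (moderate 2: 0.0837).

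The abundant liver miRNA miR-192-5p fell to 21820 ± 18140 rpm from 85224 ± 7536 at 4 h of moderate hypoxia (n = 3 each; log2 -2.59, SE 0.51, adjusted p = 0.000539). miR-150-5p (log2 -4.79, 1 measured value in moderate hypoxia), miR-181a-3p (-3.32), miR-153b-3p (-2.33) and miR-429a-3p (-2.07) fell as well. miR-210-3p (123.2 against 339 rpm, log2 -1.51), miR-210-5p (80.5 against 215.7 rpm, -1.42) and miR-462-5p (1750 against 4925 rpm, -1.56) were lower as deposited, with adjusted p = 0.0845, 0.154 and 0.0606 after rescaling. The pancreas markers (4 of 6 lower, 5 adjusted over the list alone) and stromal markers (4 of 8 lower, 5 adjusted over the list alone) were lower as deposited, with 2 and 1 lower after rescaling. miR-126b-3p was higher by log2 10.17 against a control group at 12.3 rpm, with 1 measured value in moderate hypoxia. In all 80 miRNAs (36.9% of those tested) were called, 3 higher and 77 lower (median log2 -0.51), against 37 after rescaling, 20 higher and 17 lower (median 0.07), of which 20 were shared in direction and 2 changed sign, and 40 with median-of-ratios scaling, 15 higher and 25 lower. The count was 48 without moderate library 2 and 0 with widened standard errors (101 at an unadjusted p under 0.05 in limma before widening). A single library moved by over 1.5 times the values of miR-181a-3p (moderate 1, log2 -1.92, adjusted p = 0.0119), miR-192-5p (moderate 3, log2 -1.50, adjusted p = 0.000102) and miR-429a-3p (moderate 2, log2 -1.23, adjusted p = 0.00427). Without moderate library 2 the call of miR-210-3p ended (log2 -0.92, adjusted p = 0.0598).

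The 8 h samples of moderate hypoxia had lower miR-144-3p (384 ± 220.5 against 2584 ± 1152 rpm, n = 2 each; log2 -2.80, SE 0.42, adjusted p = 0.000115) and miR-144-5p (log2 -2.05, adjusted p = 0.129 after rescaling), so that 2 of 2 erythrocyte markers fell (2 adjusted over the list alone) as in severe hypoxia. miR-462-5p fell to 2031 ± 506 from 8439 ± 2790 rpm (log2 -2.04, SE 0.35, adjusted p = 0.000226), and miR-204-5p was lower (-2.36). miR-210-3p (-1.003) and miR-210-5p (-1.45) were called as deposited, with adjusted p = 0.844 and 0.292 after rescaling. miR-205-5p was higher (39.1 against 14.0 rpm, log2 1.44). miR-126b-3p was lower (log2 -11.17), its group standing at 13.0 rpm. Most calls were lost with rescaling: 73 miRNAs (33.95% of those tested) were called, 1 higher and 72 lower (median log2 -0.56), against 11 after rescaling to the listed total, 7 higher and 4 lower (median 0.18), of which 5 were shared in direction and 21 of the 73 changed sign. Scaling by the median of ratios gave 16, 4 higher and 12 lower. The count was 38 without control library 1, 30 without moderate library 2 and 1 with widened standard errors. Calls that ended without 1 library were those of miR-205-5p (control 1, 2 or moderate 1, 2, 3: adjusted p = 0.050 to 0.203), miR-210-3p (control 1 or moderate 2: 0.182 to 0.183) and miR-210-5p (control 1 or moderate 2, log2 -0.95 without control 1, adjusted p = 0.0738 to 0.101).

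By 12 h of moderate hypoxia the differences were few. miR-193a-3p rose to 53.4 ± 0.149 from 18.9 ± 2.63 rpm (n = 2 each; log2 1.46, SE 0.31, adjusted p = 0.00994) and the muscle marker miR-133a-3p to 57.4 ± 9.85 from 17.9 ± 5.70 rpm (log2 1.65, SE 0.38, adjusted p = 0.0123). miR-137-3p (39.2 against 0.710 rpm, log2 4.51) and miR-126b-3p (log2 7.53, against a control group at 65.3 rpm) were higher, each against 1 measured control value, and let-7a-3p (-1.11) and miR-101b-5p (-0.75) were lower. miR-210-3p stood at 258 against 140 rpm (log2 0.86, adjusted p = 0.178). Called were 7 miRNAs (3.21% of those tested), 5 higher and 2 lower (median log2 0.19), 15 after rescaling, 5 higher and 10 lower (median -0.06), and 12 with median-of-ratios scaling, 5 higher and 7 lower. The count was 3 without control library 3, 2 without moderate library 2, 2 without moderate library 3 and 0 with widened standard errors (42 at an unadjusted p under 0.05 in limma before widening). Lost without 1 library were the calls of miR-133a-3p (control 3 or moderate 2, 3: adjusted p = 0.0554 to 0.191), miR-193a-3p (control 2 or moderate 2, 3: 0.0623 to 0.0799) and let-7a-3p (control 3 or moderate 1, 2, 3: 0.0554 to 0.258). The same held for miR-101b-5p (control 1, 3 or moderate 2, 3: 0.0755 to 0.117).

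After 24 h of moderate hypoxia, miR-222a-3p had 1781 ± 429.1 rpm against 740 ± 316 (n = 2 each; log2 1.31, SE 0.34, adjusted p = 0.00990). miR-155-5p (9.13 against 3.60 rpm, log2 1.35), miR-205-5p (2.08, 1 measured value in moderate hypoxia) and miR-137-3p (2.12) rose. The neuron-associated miR-9-3p fell to 2.96 from 26.2 rpm (log2 -2.68) and miR-9-5p to 24.7 from 104 rpm (-1.85), and 4 of 8 neuron markers were lower and 1 higher (6 adjusted over the list alone). miR-365-3p (-1.64) and miR-16c-3p (-1.46, 1 measured control value) were lower. miR-126b-3p differed by log2 9.22 (control group at 6.38 rpm) and miR-126a-3p by -8.11 (its own group at 11.9 rpm, 1 measured value). In total 42 miRNAs (20.2% of those tested) were called, 19 higher and 23 lower (median log2 -0.04), and 61 after rescaling, 21 higher and 40 lower (median -0.13), and 52 with median-of-ratios scaling, 23 higher and 29 lower, with 42 called the same way in both and 2 with widened standard errors. Calls ended, or values moved by over 1.5 times, without 1 library for miR-137-3p (moderate 2: adjusted p = 0.0586), miR-205-5p (control 1, 2, log2 3.14 and 1.02, adjusted p = 0.000877 to 0.234) and miR-155-5p (control 1, 2 or moderate 2, 3, log2 0.55 and 2.15 without control 1 and control 2, adjusted p = 0.00298 to 0.458). The same held for miR-222a-3p (control 2 or moderate 3, log2 0.86 without control 2, adjusted p = 0.0918 to 0.131), miR-9-5p (control 1, log2 -1.10, adjusted p = 0.144) and miR-16c-3p (moderate 2: 0.118).

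**Figure D4:**
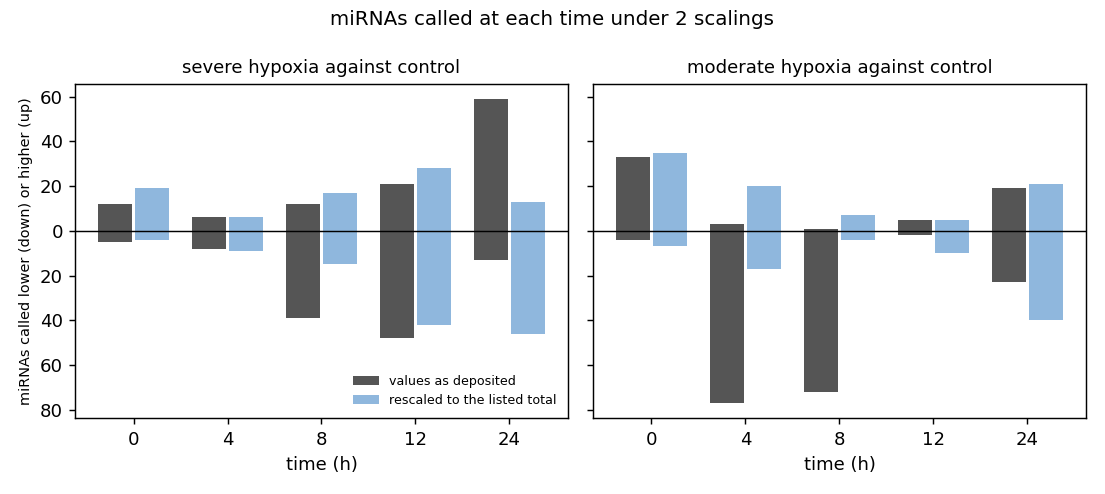
Number of miRNAs called higher (upward) and lower (downward) than control at each hour, as deposited and rescaled to the listed total, for both levels of hypoxia. As deposited, moderate hypoxia has 77 lower at 4 h and 72 at 8 h, which become 17 and 4 after rescaling.

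Severe and moderate hypoxia were compared directly to test the difference between oxygen levels. As a mean over times miR-210-5p was higher in severe hypoxia, at 262 ± 244 rpm against 102 ± 56.3 (log2 1.17, SE 0.16, adjusted p = 3.44e-05; 0.95 and 0.000241 after rescaling), in that direction at 4 of 5 times. miR-210-3p was higher as deposited (log2 0.56, SE 0.15, adjusted p = 0.0105; 0.0940 after rescaling), and miR-462-5p stood at 3692 against 3222 rpm (log2 0.34, adjusted p = 0.105). miR-181a-3p was higher (484 against 78.5 rpm, log2 1.54), and miR-181b-5p (log2 -0.43), miR-456-3p (-0.43; -0.34 and adjusted p = 0.162 without 24 h) and miR-1388-3p (-0.37) were lower. miR-126b-3p gave log2 2.04 through the group of moderate hypoxia at 13.0 rpm. Called were 51 miRNAs (26.3% of those tested), 41 higher and 10 lower (median log2 0.13), and 47 after rescaling, 17 higher and 30 lower (median -0.05), with 27 called the same way in both. Scaling by the median of ratios gave 43, 29 higher and 14 lower, and without 24 h the count as deposited was 32. With widened standard errors 0 were called, and with the spread between times as the error limma called 0 (79 and 9 at an unadjusted p under 0.05 in limma without widening). Leaving out any 1 of 7 libraries ended the call of miR-456-3p (adjusted p up to 0.0763). Without 12, 8, 4 and 0 h it was 79, 56, 45 and 85. Calls ended for miR-181b-5p (log2 -0.24), miR-456-3p (0.03) and miR-1388-3p (-0.23) without 12 h, for miR-1388-3p (-0.26) and miR-126b-3p (-0.05) without 8 h, for miR-210-3p (0.14) without 4 h and for miR-1388-3p (-0.25) without 0 h. Others moved: miR-456-3p (-0.86) and miR-1388-3p (-0.58) without 4 h, miR-210-3p (0.91) and miR-181a-3p (0.93) without 0 h, and miR-181b-5p (-0.65) without 24 h.

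At single hours the difference in miR-210-5p was called at 4 h (log2 1.23, not after rescaling), 8 h (1.32, not after rescaling), 12 h (1.84) and 24 h (1.55), and that in miR-210-3p at 4 h (2.26) and 12 h (1.09). miR-462-5p was higher in severe hypoxia at 8 h as deposited (log2 1.11, adjusted p = 0.0420; 0.209 after rescaling). At 0 h miR-181a-3p (1201 against 69.9 rpm, log2 3.97), miR-144-5p (1.62) and let-7b-3p (1.56) were higher, and the pancreas markers miR-216b-5p (-2.64), miR-216a-5p (-2.59) and miR-217-5p (-2.31) were lower. Hour 4 had higher miR-181a-3p (3.39), miR-216a-5p (3.17) and miR-107b-3p (3.04), with miR-137-3p (-2.78, 1 measured value each) and miR-2188-3p (-0.91) lower. At 8 h miR-10a-5p (4.20) and miR-7a-5p (3.96) were higher and miR-190a-3p (-1.20) and miR-1388-3p (-0.81) lower. miR-126b-3p (log2 10.40) and miR-126a-3p (-8.72) differed at 8 h, where the first was at 13.0 rpm in moderate and the second at 18.9 rpm in severe hypoxia. Lost at 0 h without 1 library were the calls of miR-144-5p (moderate 1 or severe 1: adjusted p = 0.0635 to 0.106) and miR-217-5p (severe 3: 0.0598). At 4 h calls ended or moved by over 1.5 times for miR-181a-3p (moderate 1, log2 1.99, adjusted p = 0.00928), miR-2188-3p (moderate 1, 3 or severe 2: 0.0593 to 0.181) and miR-210-5p (moderate 2 or severe 3: 0.0881 to 0.0979). At 8 h those lost without 1 library were miR-190a-3p (severe 2, log2 -0.70, adjusted p = 0.131), miR-1388-3p (moderate 3 or severe 1, 2: 0.0719 to 0.0818) and miR-210-5p (moderate 2 or severe 1, 2: 0.0575 to 0.192). The same held for miR-462-5p (moderate 1, 2 or severe 1, 2, 3: 0.0556 to 0.210).

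At 12 h miR-122-3p (609 against 87.4 rpm, log2 2.79), let-7a-3p (2.48) and miR-30c-5p (2.07) were higher in severe than in moderate hypoxia, and miR-9-5p (-2.64), let-7f-3p (-2.52) and let-7e-5p (-2.36) were lower. At 24 h miR-365-3p (35.2 against 2.50 rpm, log2 3.37) and miR-460-3p (2.87) were higher, while miR-10a-5p (-2.69), miR-122-5p (8582 against 28880 rpm, -1.68) and miR-15b-5p (-1.63) were lower. miR-126a-3p differed by log2 9.08 at 24 h, against 11.9 rpm in moderate hypoxia (1 measured value). At 24 h calls ended or moved by over 1.5 times without 1 library for miR-10a-5p (moderate 3 or severe 1, 2, log2 -4.11 and -1.27 without severe 1 and severe 2, adjusted p = 0.000161 to 0.147) and miR-15b-5p (moderate 1, 2 or severe 2: adjusted p = 0.0572 to 0.136). At 12 h the call of miR-210-3p (moderate 2 or severe 2, 3: 0.0517 to 0.127) ended.

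At 0 h 51 miRNAs were called (11 higher, 40 lower; median log2 -0.29), at 4 h 68 (65 and 3; 0.41), at 8 h 24 (19 and 5; 0.32), at 12 h 81 (19 and 62; -0.33) and at 24 h 64 (54 and 10; 0.41), which is 23.6%, 31.1%, 11.2%, 37.3% and 31.2% of those tested. After rescaling to the listed total these were 56 (24 and 32; -0.11), 60 (32 and 28; -0.19), 25 (10 and 15; -0.03), 42 (23 and 19; 0.09) and 40 (17 and 23; -0.16). With median-of-ratios scaling they were 44 (29 and 15), 51 (36 and 15), 21 (11 and 10), 44 (24 and 20) and 37 (17 and 20), so that at 0 h the balance was opposite to that of both other scalings. With widened standard errors 0, 0, 4, 0 and 2 were called (86, 86, 58, 96 and 85 at an unadjusted p under 0.05 in limma before widening). At 0 h the count was 26 without moderate library 1, 32 without moderate library 2 and 24 without severe library 3. At 8 h it was 15 without moderate library 2, 12 without severe library 1 and 13 without severe library 2, and at 12 h 40 without moderate library 2.

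The difference from control was called as changing with time for many miRNAs. In severe hypoxia miR-10a-5p had the widest range after the miR-126 pair, from log2 3.81 at 8 h to -2.12 at 24 h (range 5.93, adjusted p = 0.000150), followed by miR-7a-5p (3.85 at 8 h, -1.68 at 24 h; adjusted p = 7.36e-07) and miR-144-3p (1.68 at 0 h, -3.53 at 8 h; adjusted p = 1.72e-05). The difference in miR-210-3p ran from log2 -0.78 at 8 h to 1.94 at 12 h (adjusted p = 0.00103) and that in miR-210-5p from -0.80 at 0 h to 2.32 at 12 h (adjusted p = 0.000150). In moderate hypoxia miR-181a-3p ran from -3.91 at 0 h to 0.50 at 12 h (adjusted p = 0.00109), miR-144-3p from 0.56 at 0 h to -2.80 at 8 h (adjusted p = 0.000786) and miR-153b-3p from -2.33 at 4 h to 0.76 at 12 h (adjusted p = 0.000658). In moderate hypoxia miR-210-3p ran from -1.51 at 4 h to 0.86 at 12 h (adjusted p = 0.000786; 0.0432 after rescaling), and miR-210-5p from -1.45 at 8 h to 0.48 at 12 h, called only as deposited (adjusted p = 0.00892; 0.322 after rescaling). miR-462-5p varied in both (range 1.92 log2, adjusted p = 0.00528 in severe; 3.02 and 0.000453 in moderate hypoxia). The miR-126 pair, near 0 in the groups named above, had ranges of 10.84 and 10.39 in severe and 21.34 and 8.31 in moderate hypoxia (miR-126b-3p first). The share of tested miRNAs called was 56.2% in severe and 67.0% in moderate hypoxia, and 53.2% and 46.7% after rescaling. Median-of-ratios scaling gave 91 and 69 miRNAs. With widened standard errors 1 and 2 miRNAs were called.

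The 2 means share controls, so their overlap was set against simulated unchanged groups sharing them. Among the miRNAs tested in both, 25 were called in the same direction, 7 higher and 18 lower, and only miR-210-5p was called in opposite directions (log2 0.50 in severe, -0.67 in moderate hypoxia), in severe hypoxia not without 12 h (0.04) or 24 h (0.30) and at 0.82 without 0 h, and in moderate hypoxia not without 8 h (-0.47) or 4 h (-0.48). The severe call also ended without any 1 of 6 libraries (adjusted p up to 0.0636). The shared rises include miR-155-5p, and the shared falls miR-30a-3p, miR-19d-5p, miR-19b-3p and miR-2188-3p (in severe hypoxia -0.71 without 8 h and -1.68 without 0 h). Simulations gave 0.01 shared calls on average (1 at most), from the spread within groups alone. They leave out differences like those between control hours (median 57.5 calls after rescaling, 27 without 24 h). Independent lists of these sizes would share 1.38 higher and 8.60 lower. Across miRNAs, not independent replicates, the log2 differences correlated at 0.732, against 0.489 on average and 0.630 at most in simulations. This excess was not tested without the miR-126 pair, set by groups near 0 and among the 25. With controls split between both, the correlation lay between 0.00281 and 0.617 on 8 to 64 testable miRNAs. After rescaling 13 were shared, 7 higher and 6 lower (independent lists 2.47 and 2.03). Without 12 h 13 were shared, against 27, 18, 19 and 31 without 24, 8, 4 and 0 h.

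Among the lists, the miR-17 to miR-92 cluster, a set of growth-associated miRNAs, was lower in severe hypoxia as a mean over times: 5 of 14 tested members fell and 0 rose (6 adjusted over the list alone), with a median log2 of -0.21. The list test gave adjusted p = 0.0309 (0.0477 after rescaling), and adjusted p = 0.193 with an estimated correlation. Its members miR-19d-5p (log2 -1.57, library mean 5.56 rpm), miR-20a-3p (-0.70, 2.13 rpm), miR-19a-3p (-0.57) and miR-19b-3p (-0.50) fell. It was the only list that cameraPR called in severe hypoxia (2 without 24 h), while fry, which does not compare a list with other miRNAs, called 6. cameraPR called 0 lists without severe library 3 at 8 h or at 24 h, without 12 h or without 4 h. In moderate hypoxia 6 of its 14 members were lower and 0 higher as deposited (6 adjusted over the list alone), and 1 lower and 2 higher after rescaling (list adjusted p = 0.469). Without 12 h the calls of miR-20a-3p (-0.42) and miR-19a-3p (-0.24) ended, and miR-20a-3p was at -1.10 without 0 h.

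Lipid and glucose metabolism had 6 of 21 members higher and 0 lower in severe hypoxia (6 adjusted over the list alone; adjusted p = 0.0845), among them miR-27c-5p. The hypoxia-associated list had 8 of 32 higher and 3 lower (11 adjusted over the list alone; adjusted p = 0.531), led by miR-155-5p. Neuron markers had 4 of 7 lower (5 adjusted over the list alone; adjusted p = 0.141): miR-9-5p, miR-219-5p (library mean 1.35 rpm), miR-138-5p (2.39 rpm) and miR-128-3p, of which 0 were called without 12 h (log2 -0.50, -0.42, -0.40 and -0.12), and miR-219-5p and miR-138-5p not without 24 h (-0.46 and -0.22). Angiogenesis and endothelium had 4 of 26 higher and 7 lower (12 adjusted over the list alone; adjusted p = 0.531; the list holds the miR-126 pair and 14 members of the miR-17 to miR-92 cluster). The miR-30 family had 2 of 7 higher and 3 lower (5 adjusted over the list alone; adjusted p = 0.833), with miR-30a-3p (-0.82) the lowest. The call of miR-128-3p also ended without control library 3 at 4 h (adjusted p = 0.0526).

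The other lists in severe hypoxia were the miR-23, miR-27 and miR-24 clusters (3 of 13 higher, 1 lower; 4 adjusted over the list alone; adjusted p = 0.512), inflammation (2 of 15 higher, 2 lower; 4 adjusted over the list alone; adjusted p = 0.912) and the let-7 family (1 of 16 higher, 3 lower; 3 adjusted over the list alone; adjusted p = 0.912). Liver-enriched miRNAs had 1 higher and 1 lower of 7 (2 adjusted over the list alone; adjusted p = 0.833), and p53 and apoptosis had 2 of 15 higher (2 adjusted over the list alone; adjusted p = 0.694). Leukocyte markers had 1 of 5 higher, miR-155-5p (3 adjusted over the list alone; adjusted p = 0.800). Stromal markers had 1 of 8 higher (0 adjusted over the list alone; adjusted p = 0.267), and epithelium markers 1 of 10 (0 adjusted over the list alone; adjusted p = 0.833). Pancreas markers had 0 of 5 called (0 adjusted over the list alone; adjusted p = 0.833). Too small for the list test, erythrocyte markers had 1 of 2 lower (2 adjusted over the list alone), the miR-183 cluster 0 of 2 (1 adjusted over the list alone) and muscle markers 0 of 1.

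No list was called in moderate hypoxia by cameraPR (1 without 24 h, and 11 by fry), where 2 had an unadjusted p under 0.05. These were the miR-30 family, with 5 of 7 lower as deposited and 1 after rescaling (5 adjusted over the list alone; adjusted p = 0.155), and leukocyte markers, with 2 of 5 higher, led by miR-155-5p (2 adjusted over the list alone; adjusted p = 0.155). As deposited the let-7 family had 6 of 16 lower (7 adjusted over the list alone; adjusted p = 0.469), p53 and apoptosis 8 of 16 lower and 1 higher (9 adjusted over the list alone; adjusted p = 0.605), the hypoxia-associated list 8 of 32 lower and 2 higher (7 adjusted over the list alone; adjusted p = 0.545) and liver-enriched miRNAs 3 of 7 lower (3 adjusted over the list alone; adjusted p = 0.545). After rescaling these had 0, 0, 2 and 0 lower, and the hypoxia-associated list 5 higher.

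Lipid and glucose metabolism had 4 of 19 lower and 2 higher in moderate hypoxia (3 adjusted over the list alone; adjusted p = 0.469), with 0 lower and 3 higher after rescaling. Angiogenesis and endothelium had 7 of 25 lower and 2 higher (9 adjusted over the list alone; adjusted p = 0.977), with 2 lower and 4 higher after rescaling. Inflammation had 1 of 15 higher and 2 lower (3 adjusted over the list alone; adjusted p = 0.469), with 2 higher and 1 lower after rescaling, and the miR-23, miR-27 and miR-24 clusters 1 of 13 higher and 2 lower (0 adjusted over the list alone; adjusted p = 0.329), with 3 higher and 0 lower after rescaling. Neuron markers had 3 of 6 lower (3 adjusted over the list alone; adjusted p = 0.545) and stromal markers 2 of 8 lower (0 adjusted over the list alone; adjusted p = 0.924), both with 0 after rescaling. Epithelium markers had 2 of 10 higher (1 adjusted over the list alone; adjusted p = 0.469), and pancreas markers 1 of 5 lower (0 adjusted over the list alone; adjusted p = 0.545), 0 after rescaling. Erythrocyte markers had 2 of 2 lower (2 adjusted over the list alone), 1 after rescaling, the miR-183 cluster 1 of 2 lower (1 adjusted over the list alone), 0 after rescaling, and 1 of 1 muscle markers was higher (1 adjusted over the list alone). Without moderate library 1 at 8 h, 1 list was called.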

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

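The tests of chance equality and no-read libraries, the 3 tests of the miR-126 pair with the comparison of its -5p arms, the counts between control hours and the simulated closest pairs at 1 log2 were chosen after the result was seen. The first paragraphs give results picked out because the F-test of the interaction called a change of the difference from control with time.

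In severe hypoxia 56.2% of the tested miRNAs were called, and 1 miRNA with widened standard errors. The widest ranges between times were 10.84 log2 for miR-126b-3p, 10.39 for miR-126a-3p, 5.93 for miR-10a-5p, 5.52 for miR-7a-5p and 5.22 for miR-144-3p. In moderate hypoxia the share was 67.0%, and 2 miRNAs with widened standard errors, with ranges of 21.34 for miR-126b-3p, 8.31 for miR-126a-3p, 4.41 for miR-181a-3p, 3.37 for miR-144-3p and 3.09 for miR-153b-3p. The ranges of the miR-126 pair are set by groups near 0, weighed below.

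Regrouping the libraries tested whether chance can give such counts. The values were averaged inside the real groups, and if the value farthest from the others was replaced, which stays open, the real grouping has too little spread and stands apart from other splits whatever the biology. Simulated unchanged libraries with a spread of 0.6 log2 then gave a mean of 69.2 false calls for the mean over times, so the splits cannot exclude chance. For the change over time, 1 of 100 splits, the real one, reached the real count in severe hypoxia (113 called, highest other split 45), moderate hypoxia (1.3e+02 called, rounded to 2 significant digits, highest other 52) and the control group (163 called, highest other 97). For the means over times it was again 1 of 100 splits: 53 called in severe hypoxia (highest other 9), 74 in moderate hypoxia (28) and 51 in severe against moderate (39), while widened standard errors left 3, 1 and 0 (80, 83 and 79 at an unadjusted p under 0.05 in limma before widening). For single times the 10 splits of 6 libraries are too few for a share under 0.05. The real counts and highest others at 0, 4, 8, 12 and 24 h were 17 and 7, 14 and 5, 51 and 12, 69 and 15, and 72 and 20 in severe hypoxia. In moderate hypoxia they were 37 and 11, 80 and 32, 73 and 26, 7 and 3, and 42 and 8, and in severe against moderate 51 and 28, 68 and 64, 24 and 3, 81 and 35, and 64 and 9. In each case the real split was the 1 that reached its count.

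In most groups of 3 libraries, 1 value is the mean of the other 2. Chance equality of independent measurements is argued against: of 1744 sets with a range of at least 10 rpm the middle value sat at the middle of the range in 1662, against 0 at 0.4 or 0.6 of it. Replacement of the library farthest from the other 2 stays open: the squared difference of the 2 measured values was 1.31 times its counting variance on average (95% interval 1.07 to 1.56, 432 pairs), which the test as planned read as against it, but simulated closest pairs gave 0.728 at a spread of 0.6 log2 and 1.51 at 1 log2, and the median of 0.34 lies below the 0.407 of random pairs with counting noise alone. Replacement of libraries with no reads is a candidate explanation for low values, since among 488 sets with under 3 reads on average 3 hold a 0 beside a value above 0, against 246 predicted from the counts. Whether it holds for abundant miRNAs was not tested, so their rule stays open, and no biological explanation was tested.

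The -3p arm of miR-126a or miR-126b is near 0 in some groups and abundant in all others. A change in the whole precursor stays open: the -5p arm kept a median of at least 0.761 of its level in the other groups, but both -5p arms were within 5% of each other in 3 of the 6 low groups (3 of the 9 others), so their reads may be shared. Reads moved between the -3p arms are argued against, since where one was low the other's median was at most 0.971 of its level elsewhere. Single groups can be higher. Oxygen level alone is argued against, since groups of 1 oxygen level lie on both sides: miR-126b-3p was low in 3 of 5 control, 1 moderate and 0 severe groups, and miR-126a-3p in 0 control, 1 moderate and 1 severe group. An effect of oxygen that depends on the hour stays open, as does a step in read assignment or table making that differed between groups.

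Many miRNAs were called at single times, yet with time as block limma called 0 in each mean comparison (10, 10 and 9 at an unadjusted p under 0.05). Differences between sets of libraries that oxygen does not set may account for some of these calls. After listed-total scaling, the 10 pairs of control hours had a median of 57.5 calls (5 to 91), and the 10 comparisons of hypoxia with control at the same hour had 34.5 (11 to 70). Without the control group at 24 h the median was 27 and the highest 62. The hours of the control group also differ in time and fasting, so a change of the fish over time stays open, as does an effect of oxygen that depends on the hour.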

How the results depend on the processing

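The alternatives that count all 3 values, keep groups at 0, widen the standard errors, use time as block or leave out a time were chosen after seeing the data, and the others were planned. Counts are of called miRNAs, values are log2 differences, and where a count or sign moved the cause was not tested unless stated. Precision is limited by 2 measured values per group and by an inferred depth of 1.01 to 5.57 mega-reads per library. Of 220 named miRNAs in their comparisons, all called, the call held in 193 with median-of-ratios scaling, in 176 with listed-total scaling, in all but 1 with no filter, in 211 with a pseudocount of 0.1, in 212 with a pseudocount of 10, in 188 with only the groups compared and in 16 with widened standard errors, and the others kept their direction. The filter of at least 10 rpm in at least 3 libraries kept all 209 it could test, and leaving out 1 library kept 3219 of 3600. Leaving out 24 h kept 68 of 95, with 26 no longer called and 1 reversed, and leaving out 12, 8, 4 or 0 h kept 58, 62, 69 and 85, with 3, 2, 0 and 0 reversed. Time as block kept 0 of 93. The planned count-based tools were not run, since the values are not counts.

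Median-of-ratios scaling gave 33 miRNAs for severe hypoxia at 8 h, 40, 16 and 12 for moderate hypoxia at 4, 8 and 12 h and 49 as a mean, 44 and 37 for severe against moderate at 12 and 24 h, and 69 for the change over time in moderate hypoxia. The sign reversed for miR-210-5p in severe hypoxia at 8 h (0.18), miR-462-5p in moderate hypoxia at 24 h (-0.030), miR-210-3p in moderate hypoxia as a mean (0.030), and in severe against moderate for miR-210-5p (0.24) and miR-462-5p (0.12) at 0 h, miR-462-5p at 4 h (-0.11), miR-210-3p at 8 h (-0.021), miR-462-5p at 12 h (0.36) and miR-210-3p at 24 h (-0.37).

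Listed-total scaling gave 32 for severe hypoxia at 8 h, 37, 11 and 15 for moderate hypoxia at 4, 8 and 12 h and 33 as a mean, 42 and 40 for severe against moderate at 12 and 24 h, and 13 shared calls. The sign reversed for miR-210-3p (0.056) at 0 h, miR-210-5p (0.30) at 8 h, and miR-210-3p (-0.12) and miR-462-5p (-0.097) at 24 h of severe hypoxia, and for miR-462-5p at 24 h (-0.089) and miR-210-3p as a mean (0.15) in moderate hypoxia. In severe against moderate it reversed for miR-210-5p at 0 h (0.067), miR-462-5p at 4 h (-0.35), miR-210-3p at 8 h (-0.19), miR-462-5p at 12 h (0.40), and miR-210-3p (-0.51) and miR-462-5p (-0.0088) at 24 h. With the most abundant miRNA, miR-26a-5p, left out of the total, the counts in the same order were 30, 39, 11, 12, 33, 43, 38 and 13. The same signs reversed except the last, at 0.021, 0.25, -0.092, -0.063, -0.065, 0.16, 0.065, -0.46, -0.19, 0.43 and -0.50.

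With all 3 deposited values counted, which counts averaged values as measurements, the counts at 0, 4, 8, 12 and 24 h and for the mean were 87, 78, 105, 136, 147 and 121 in severe hypoxia. In moderate hypoxia they were 1.3e+02, 1.5e+02, 152 (moderate hypoxia against control at 8 h), 90, 118 and 118, and in severe against moderate 131, 1.3e+02, 111, 1.3e+02, 1.4e+02 and 118, the exponents rounded to 2 significant digits. The change over time in severe hypoxia had 184, 56 calls were shared, and miR-462-5p in moderate hypoxia against control at 24 h was -0.0096. Widened standard errors (2.39 times), a stricter test by construction, gave in the same order 0, 1, 3, 0, 0 and 3, then 0, 0, 1, 0, 2 and 1, then 0, 0, 4, 0, 2 and 0. They gave 1, 2 and 15 for the change over time in severe hypoxia, moderate hypoxia and control, and 1 shared call.

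With only the groups compared in the fit, 2 miRNAs were called in severe hypoxia at 0 h and 9, 28, 27 and 18 in moderate hypoxia at 0, 4, 12 and 24 h. A pseudocount of 0.1 gave 9 in severe hypoxia at 4 h, and a pseudocount of 10 gave 17 in moderate hypoxia at 12 h. Groups at 0 kept as values gave 16 in moderate hypoxia at 12 h. The filter of at least 10 rpm in at least 3 libraries gave 25 in moderate hypoxia at 24 h. Leaving out 24 h gave 32 for severe against moderate as a mean, against 79 without 12 h and 85 without 0 h. Without 12 h 25 were called in severe hypoxia as a mean and 13 shared, and without 8 and 4 h 42 and 47 in moderate hypoxia. As a mean, signs reversed in severe hypoxia for miR-126a-3p (0.26) without 8 h, let-7e-5p (0.066) and let-7j-5p (0.042) without 12 h and miR-462-5p (0.016) without 4 h. They also reversed in moderate hypoxia for miR-210-3p without 8 h (0.14) and 4 h (0.27), and in severe against moderate for miR-126b-3p without 8 h (-0.045) and miR-456-3p without 12 h (0.030). Without 24 h the sign turned for miR-27b-3p in moderate hypoxia against control, mean over the 5 times, at -0.0049. Time as block, which takes the spread between times as the error, gave 0 for each of the 3 means and 0 shared calls (10, 10 and 9 at an unadjusted p under 0.05 in limma), and with listed-total scaling 0, 0, 0 and 0 (12, 9 and 15 at an unadjusted p under 0.05), with miR-210-3p in moderate hypoxia as a mean at 0.15.

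Of the lists, severe hypoxia had 2 called by cameraPR with a pseudocount of 0.1, 2 with time as block and 2 without 24 h. It had 0 without 12 h, 0 without 4 h, 0 with only the groups compared, 0 with a pseudocount of 10, 0 with groups at 0 kept, 0 with the filter of at least 10 rpm, 0 with an estimated correlation and 0 with time as block and listed-total scaling. Moderate hypoxia had 1 without 24 h. fry, which counts averaged values, gave 6 in severe and 11 in moderate.

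The replicate numbers, tried as a block of pairs, turned miR-462-5p in severe against moderate hypoxia at 12 h to 0.12, and 12 of the 220 calls were lost with their direction kept. The numbers do not pair the libraries: over 315 pairs with the same number the correlation of residuals lay between -0.266 and 0.285 (median 0.0011, 29 over 0.1), against a median of 0.0034 for other numbers, and 20 of 45 libraries correlated best with a library of their own number.

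Leaving out 1 library, which has fewer values by construction and where a lone measured value is assumed to vary like the other groups, gave 8 to 16 miRNAs in severe hypoxia at 0 h, 5 to 11 at 4 h and 47 to 74 at 24 h. It gave 13 to 40, 48 to 99, 30 to 67 and 2 to 7 in moderate hypoxia at 0, 4, 8 and 12 h, and 24 to 57, 12 to 22 and 40 to 73 in severe against moderate at 0, 8 and 12 h. Lists called were 0 to 1 in severe and 0 to 1 in moderate hypoxia. In severe hypoxia miR-210-3p at 0 h ran from -0.39 to 0.21, miR-210-5p at 4 h from -0.43 to 0.048 and at 8 h from -0.63 to 0.37, and miR-462-5p at 12 h from -0.77 to 0.077. In moderate hypoxia miR-210-5p at 24 h ran from -0.60 to 0.071, miR-462-5p at 24 h from -0.40 to 0.41 and miR-210-3p as a mean from -0.20 to 0.032. In severe against moderate miR-210-5p at 0 h ran from -0.39 to 0.16, miR-462-5p at 4 h from -0.088 to 0.83, miR-210-3p at 8 h from -0.038 to 0.49 and miR-462-5p at 12 h from -0.55 to 0.30.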

Other observations

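The miRNAs in the first 3 paragraphs were chosen after the result was seen, while the test of arm ratios was planned before.

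At 12 h of severe hypoxia 8 of 14 tested members of the miR-17 to miR-92 cluster were lower than in control and 0 higher (8 adjusted over the list alone), with 6 lower after rescaling. Lower were miR-19a-3p (log2 -1.91, SE 0.22, adjusted p = 2.43e-06), miR-20a-3p (-1.81, library mean 2.13 rpm), miR-19d-5p (-1.81, 5.56 rpm), miR-19b-3p (-1.16), miR-18a-3p (-1.11), miR-92a-3p (-0.90, not called after rescaling), miR-18a-5p (-0.81) and miR-19d-3p (-0.61, not called after rescaling). At this hour limma called 0 miRNAs with widened standard errors, with 81 at an unadjusted p under 0.05 before widening.

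Severe and moderate hypoxia differed at 0 h in epithelium and at 0 and 4 h in pancreas markers. At 0 h, 5 of 11 tested epithelium markers were lower in severe hypoxia (6 adjusted over the list alone; 4 lower after rescaling), among them miR-200b-5p (log2 -1.37), miR-141-3p (-1.22) and miR-200a-3p (-1.08), of which median-of-ratios scaling called only miR-200b-5p (adjusted p = 0.0259, 0.148 and 0.146). The pancreas markers turned: miR-216a-5p, miR-216b-5p and miR-217-5p were lower in severe hypoxia at 0 h and higher at 4 h (log2 3.17, 2.87 and 2.82), 3 of 7 tested (3 adjusted over the list alone; 3 after rescaling). Whether list counts differ between hours was not tested, and with widened standard errors limma called 0 miRNAs at 0 and 4 h (86 each at an unadjusted p under 0.05 before widening).

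Some miRNAs listed at 0 in whole groups were abundant in every other group. Of the 68 miRNAs at 0 in at least 1 group, 17 were above 20 rpm in some group, and 12 were above 20 rpm in every group where they were not at 0. miR-15a-5p was at 0 in 6 groups and between 225 and 553 rpm in the others, and miR-221-5p at 0 in 4 groups and between 784 and 5545 rpm in the others.

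A hypothesis of its own was that oxygen level shifts the ratio of the 5p to the 3p arm of a precursor, tested over 39 precursors with both arms at a mean of at least 10 rpm, with time as block. limma called 0 of 39 in the mean over times of each of the 3 comparisons, with 0 at an unadjusted p under 0.05 in severe hypoxia, 3 in moderate hypoxia and 3 in severe against moderate. The smallest adjusted p was 0.0645, for miR-22b in severe against moderate (log2 0.78, SE 0.19). A count of 0 does not show that the ratios were equal, although the test as planned read it so: the 95% interval stayed within 1 log2 for 20, 20 and 18 of the 39 precursors in the same order.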
